A study of Mus musculus with 12 samples.

How the data were processed

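Per the labels' protocols, mesenchyme of the bladder and the pelvic urethra was freed from epithelium by cold trypsin treatment and dissection, female embryos of a litter were pooled, and poly(A)-selected directional libraries were sequenced as read pairs of 100 bp on an Illumina NovaSeq. The submitters' processing notes name bcl2fastq, HISAT2 2.2.1, SAMtools 1.9 and the GRCm38 genome. The counting tool, its strand setting and the gene annotation are not stated. The deposited values are raw counts per gene, not normalized, in 1 table per stage with 6 libraries each, and per the file headers each row also gives the exon coordinates and summed exon length of a gene symbol. Both tables list the same 55228 genes. Of these symbols, 53569 occur in GENCODE mouse release 21, 53261 of them at the same position. Totals ranged from 21495169 to 36349777 counts, so 3 counts correspond to 0.0825 to 0.1396 CPM. A value of 2 was 2.06 to 2.51 times as frequent as a value of 1, as arises when both reads of a pair are counted, so counting intervals and floors, which cover counting error only, are narrower than those of independent fragments. The 37 mitochondrial genes held 0 counts in all libraries.

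Genes were kept by edgeR 4.0.16 filterByExpr (minimum count 10), which left 18805, scaled by TMM and tested by robust quasi-likelihood F tests in R 4.3.3. One model of 4 group means over 12 libraries gave 8 residual degrees of freedom and all comparisons: bladder against urethral mesenchyme at each stage, the change of that difference between stages, and E18.5 against E14.5 in each compartment. Benjamini-Hochberg adjustment was made within each comparison, with adjusted p under 0.05 as the threshold. Gene lists, 36 in number, were fixed before the data were examined. Those with at least 3 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists within a comparison. The mitochondrial and Y-linked lists had 0 tested genes. With the correlation between genes estimated from the residuals, 0 of the 76 list calls among 170 list results held (smallest adjusted p = 0.222), and fry, which tests whether a list's genes move on balance, was run as a further alternative.

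Named genes followed a rule fixed before the data were examined: for each compartment comparison the 6 genes with the largest fold in each direction among those past the threshold, with at least 5 CPM in the higher group and no overlap between the groups' libraries, leaving out predicted genes, pseudogenes and clone names. For the change of the difference it gave 5 per direction, with the level taken from the highest group and overlap allowed, and for each stage comparison 4. For each list it gave up to 4 members with the largest change past the threshold and the most abundant member not past it. For length, the text names part of the genes the rule gives, chosen after their values were seen. Results of some genes are not reported here. Where a group had no counts, folds are lower bounds against 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact binomial 95% interval.

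Alternatives were DESeq2 1.42.0, limma-voom, edgeR with median-ratio size factors, no low-count filter, a stricter filter (mean of at least 1 CPM and 10 counts in every library of a group), leaving out each library in turn, fitting only the libraries compared, and replicate number as a block. Leaving out replicate 1 of both E14.5 groups was added after the data had been seen. Litters gave both bladder and urethral samples. Column names count same-numbered bladder and urethral libraries consecutively, but no label calls a replicate number a litter. Deviations of same-numbered E18.5 libraries from their group means correlated at 0.197, 0.193, 0.286 (replicates 1 to 3), over 0.1 in every pair. The numbers were therefore taken to pair the E18.5 samples. The results as reported come from the fit without that block. The scripts were tested on simulated data made from the real means, library sizes and dispersions, with 200 genes changed, in 1 simulated set per comparison. For bladder against urethral mesenchyme at E14.5, edgeR recovered 57% of 2-fold and 86% of 4-fold changes on 18473 genes, with 4.03% false calls. For the change of the difference it recovered 23% and 74% on 18488 genes, with 5.83%. In the same sets DESeq2 made 18.5% and 22.1% false calls, more than its threshold aims at. No library was left out of the results as reported.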

Results

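RNA was sequenced from mesenchyme of the bladder and pelvic urethra of female mouse embryos at 2 stages, E14.5 and E18.5, in days after conception, with 3 libraries in each of 4 groups and each library made from pooled embryos of 1 litter. Total counts per library ranged from 21495169 to 36349777. Levels are counts scaled to the TMM-adjusted library total (CPM), mean ± SD over the 3 libraries of a group. Log2 differences are given ± SE, positive where bladder or E18.5 was higher, with adjusted p from edgeR's quasi-likelihood test. After each gene list, parentheses give the calls when p is adjusted within the list alone, the adjusted p of camera, a test of the list against all other genes, and, where that is called, its adjusted p with the correlation between genes estimated from the data. With that estimate, 0 of the 76 list calls held, so each rests on the preset correlation. The first principal component held 44.7% of the variance and the second 30.9%. Replicate 1 of both E14.5 groups lay nearer the E18.5 libraries on the first component than replicates 2 and 3 of its group.

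**Figure D1:**
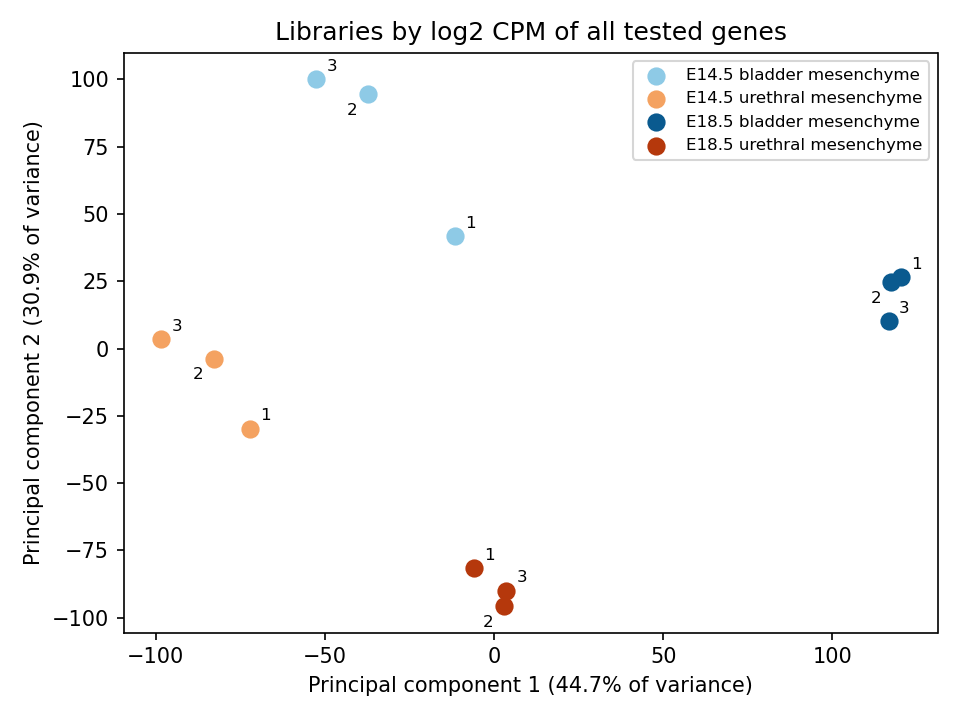
Each point is 1 of 12 libraries, numbered by replicate and colored by group, placed by the first and second principal components of log2 CPM (44.7% and 30.9% of the variance).

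The comparison of bladder with urethral mesenchyme at E14.5 asked which genes mark each compartment, the stated aim of the study. Bladder mesenchyme was higher in called smooth muscle (15 of 20 tested) and mesothelial genes (5 of 8), and urethral mesenchyme in called patterning transcription factors (18 of 35, 6 opposite), retinoic acid genes (10 of 14) and Hedgehog targets (5 of 7). Popdc2, a membrane protein of muscle, was higher in bladder (88.4 ± 9.501 against 1.84 ± 0.783 CPM, log2 difference 5.56 ± 0.31, adjusted p = 3.29e-06), as were Pln, an inhibitor of the muscle calcium pump (log2 difference 6.80 ± 0.69, adjusted p = 8.87e-05), and Gata4, a zinc finger transcription factor (log2 difference 5.32 ± 0.41, adjusted p = 2.36e-05). In urethral mesenchyme the homeobox genes Irx2 (0.401 ± 0.329 against 19.1 ± 10.2 CPM, log2 difference -5.58 ± 0.62, adjusted p = 0.000151) and Barx2 (log2 difference -4.72 ± 0.70, adjusted p = 0.0011) and the transcription factors Sp8 (log2 difference -5.34 ± 0.97, adjusted p = 0.00283) and Foxa2 (log2 difference -4.82 ± 0.63, adjusted p = 0.000345) were higher. Of 18805 genes tested, 2335 were higher in bladder and 2342 in urethral mesenchyme, of which 890 and 1369 differed at least 2-fold. Across genes, the E14.5 log2 differences correlated with summed exon length at Spearman's rho = -0.212, longer genes tending to be higher in urethral mesenchyme, against -0.05996 at E18.5 and 0.124 for the change between stages. Barx2 ranked the E14.5 libraries as the keratin Krt5 did. Whether a length bias or residual epithelium adds to the E14.5 differences, such as those of Barx2 and Foxa2, was not tested. In GRCm38, Popdc2 lies on chromosome 16 from 38362209 to 38378216 and Irx2 on chromosome 13 from 72628820 to 72634198. Opposite-strand exons cover 64.7% of those of Pln, and whether counting used strand is not stated, so its level is uncertain. With bladder replicate 1 left out, log2 differences were 6.16 for Pln, -6.47 for Irx2, -5.65 for Barx2 and -5.76 for Foxa2, and Sp8 differed at least 146-fold instead of 45.1-fold. Log2 differences were -4.74 for Sp8 without bladder replicate 2 and -3.83 for Barx2 without urethral replicate 1. Without urethral replicate 2, they were 7.74 for Pln and 6.01 for Gata4. Folds here are ratios of summed counts.

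Of contractile smooth muscle genes, 15 of 20 tested members were higher in bladder and 0 higher in urethral mesenchyme (17 and 0 within the list, camera adjusted p = 5.51e-08, 0.431 with estimated correlation). Kcnmb1, a subunit of the large-conductance potassium channel (27.2 ± 2.95 against 3.46 ± 1.21 CPM, log2 difference 2.98 ± 0.25, adjusted p = 2.99e-05) and the actin-binding protein Tpm2 (log2 difference 1.78 ± 0.25, adjusted p = 0.000532) were among them, while Des was not called (164 ± 119 against 61.3 ± 48.6 CPM, adjusted p = 0.105). Receptors and channels of bladder muscle went both ways, and 6 of 17 tested members were higher in bladder and 2 higher in urethral mesenchyme (6 and 4 within the list, camera adjusted p = 0.235). An example was the muscarinic receptor Chrm2 (log2 difference 3.48 ± 0.56, adjusted p = 0.00171), higher in bladder. Among fibrillar and network collagens, 7 of 16 tested members were higher in bladder and 0 higher in urethral mesenchyme (8 and 0 within the list, camera adjusted p = 0.0018, 0.545 with estimated correlation). An example was Col1a1 (7149.8 ± 1791 against 1979.8 ± 411 CPM, log2 difference 1.85 ± 0.20, adjusted p = 0.000121). Of elastic fibre and matrix proteoglycan genes, 11 of 25 tested members were higher in bladder and 2 higher in urethral mesenchyme (12 and 2 within the list, camera adjusted p = 0.0124, 0.545 with estimated correlation). Tnxb, a tenascin, was higher in bladder (log2 difference 3.48 ± 0.50, adjusted p = 0.00103) and its relative Tnc in urethral mesenchyme (log2 difference -2.53 ± 0.52, adjusted p = 0.0061). Of cell division genes, 12 of 24 tested members were higher in bladder and 0 higher in urethral mesenchyme (14 and 0 within the list, camera adjusted p = 8.78e-06, 0.542 with estimated correlation). An example was Tyms (log2 difference 0.81 ± 0.14, adjusted p = 0.00213). Log2 differences were 2.88 for Tnxb and -3.17 for Tnc without bladder replicate 1. The list call ended for elastic fibre genes without urethral replicate 2 (camera adjusted p = 0.0765).

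Patterning genes also differed. Of posterior Hox genes, 0 of 14 tested members were higher in bladder and 7 higher in urethral mesenchyme (0 and 8 within the list, camera adjusted p = 0.000138, 0.361 with estimated correlation). Examples were Hoxd13 (80.2 ± 5.64 against 239 ± 42.5 CPM, log2 difference -1.57 ± 0.14, adjusted p = 4e-05) and Hoxa13 (log2 difference -1.06 ± 0.15, adjusted p = 0.00049). Of anterior Hox genes, 1 of 22 tested members were higher in bladder and 5 higher in urethral mesenchyme (1 and 5 within the list, camera adjusted p = 0.00714, 0.545 with estimated correlation). An example was Hoxd1 (log2 difference -4.26 ± 0.78, adjusted p = 0.00231). Of mesenchymal patterning transcription factors, 6 of 35 tested members were higher in bladder and 18 higher in urethral mesenchyme (7 and 18 within the list, camera adjusted p = 0.0023, 0.361 with estimated correlation). Six2 (5.14 ± 2.02 against 57.9 ± 17.4 CPM, log2 difference -3.49 ± 0.31, adjusted p = 4.61e-05) was higher in urethral mesenchyme. Of retinoic acid genes, 0 of 14 tested members were higher in bladder and 10 higher in urethral mesenchyme (1 and 12 within the list, camera adjusted p = 8.68e-05, 0.355 with estimated correlation). Examples were Stra6, a receptor that takes up retinol (25.2 ± 8.04 against 129 ± 20.8 CPM, log2 difference -2.36 ± 0.37, adjusted p = 0.00134), and Crabp2, a retinoic acid carrier (log2 difference -1.33 ± 0.15, adjusted p = 0.000144). Of Hedgehog targets, 0 of 7 tested members were higher in bladder and 5 higher in urethral mesenchyme (0 and 5 within the list, camera adjusted p = 0.00169, 0.431 with estimated correlation). An example was Foxf2 (log2 difference -2.35 ± 0.26, adjusted p = 0.000143). Sex steroid genes went both ways, and 2 of 11 tested members were higher in bladder and 5 higher in urethral mesenchyme (2 and 6 within the list, camera adjusted p = 0.101). Without bladder replicate 1, Hoxd1 differed 109-fold instead of 22.4-fold (counting interval 29.96 to 903). Folds here are ratios of summed counts. The list call ended for anterior Hox genes without bladder replicate 2 (camera adjusted p = 0.0605). The list call arose for sex steroid genes without bladder replicate 1 (camera adjusted p = 0.0239).

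Secreted signals also differed at E14.5. Of Wnt and R-spondin ligands, 3 of 18 tested members were higher in bladder and 6 higher in urethral mesenchyme (3 and 6 within the list, camera adjusted p = 0.0658). Examples were Wnt5a (38.1 ± 14.6 against 189.5 ± 32.98 CPM, log2 difference -2.32 ± 0.25, adjusted p = 0.000142) and Rspo2 (log2 difference -3.17 ± 0.49, adjusted p = 0.00122), both higher in urethral mesenchyme. Of canonical Wnt targets, 2 of 13 tested members were higher in bladder and 6 higher in urethral mesenchyme (2 and 7 within the list, camera adjusted p = 0.0561). Of secreted Wnt antagonists, 3 of 11 tested members were higher in bladder and 2 higher in urethral mesenchyme (3 and 2 within the list, camera adjusted p = 0.838). Sostdc1 was higher in bladder (log2 difference 2.48 ± 0.34, adjusted p = 0.000523) and Dkk2 in urethral mesenchyme (log2 difference -2.82 ± 0.52, adjusted p = 0.00351). Of BMP and GDF ligands, 1 of 13 tested members were higher in bladder and 5 higher in urethral mesenchyme (3 and 8 within the list, camera adjusted p = 0.0324, 0.542 with estimated correlation). Of secreted BMP antagonists, 2 of 11 tested members were higher in bladder and 4 higher in urethral mesenchyme (2 and 4 within the list, camera adjusted p = 0.579). Bmp7 (log2 difference -1.58 ± 0.21, adjusted p = 0.00033) and the antagonist Nog (log2 difference -2.73 ± 0.30, adjusted p = 0.000136) were higher in urethral mesenchyme. With bladder replicate 1 left out, log2 differences were -4.14 for Rspo2 and -3.61 for Dkk2. The log2 difference was -2.20 for Dkk2 without urethral replicate 1. The list call ended for BMP ligand genes without bladder replicates 2 or 3 or urethral replicate 1 (camera adjusted p = 0.0605 to 0.129). List calls arose for Wnt target genes without bladder replicates 1 or 2 or urethral replicate 2 (camera adjusted p = 0.0105 to 0.0471) and Wnt ligand genes without bladder replicate 1 or urethral replicate 2 (adjusted p = 0.00619 to 0.0476).

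Markers of other cell types differed as well. Of mesothelial genes at E14.5, 5 of 8 tested members were higher in bladder and 0 higher in urethral mesenchyme (5 and 0 within the list, camera adjusted p = 0.000856, 0.431 with estimated correlation). Examples were Upk3b (log2 difference 4.98 ± 0.60, adjusted p = 0.00037) and Muc16 (log2 difference 5.05 ± 0.75, adjusted p = 0.00105). Of neuronal genes, 0 of 14 tested members were higher in bladder and 12 higher in urethral mesenchyme (0 and 13 within the list, camera adjusted p = 1.67e-05, 0.542 with estimated correlation). An example was Dbh, the enzyme that makes noradrenaline (log2 difference -2.31 ± 0.49, adjusted p = 0.00732). Of glial genes, 0 of 10 tested members were higher in bladder and 5 higher in urethral mesenchyme (0 and 6 within the list, camera adjusted p = 0.00714, 0.545 with estimated correlation). An example was Sox10 (log2 difference -1.74 ± 0.34, adjusted p = 0.00333). Of endothelial genes, 3 of 15 tested members were higher in bladder and 0 higher in urethral mesenchyme (3 and 0 within the list, camera adjusted p = 0.00714, 0.545 with estimated correlation). Epithelial genes were present in these mesenchyme libraries, with a summed level of 952 ± 880.1 CPM in bladder and 1555 ± 687 in urethral mesenchyme. Replicate 1 carries the bladder mean, which was 447 CPM without it. Of these, 2 of 22 tested members were higher in bladder and 5 higher in urethral mesenchyme (3 and 9 within the list, camera adjusted p = 0.0141, 0.619 with estimated correlation): the basal keratin Krt5 was higher in urethral mesenchyme (16.2 ± 22.97 against 278 ± 194 CPM, log2 difference -4.11 ± 0.98, adjusted p = 0.0129). Its bladder mean was 2.92 CPM without replicate 1. Of skeletal muscle genes, 0 of 20 tested members were higher in bladder and 5 higher in urethral mesenchyme (2 and 6 within the list, camera adjusted p = 0.0971). Their summed level was 121 ± 152 CPM in bladder and 95.7 ± 103 in urethral mesenchyme, and 34.03 and 36.01 CPM without replicate 1 of each. The count of genes higher in bladder was 1460 without bladder replicate 3, 1403 without urethral replicate 3 and 1384 when the 6 libraries were fitted alone. That higher in urethral mesenchyme was 1395 without bladder replicate 2 and 1261 without bladder replicate 3. Without bladder replicate 1, log2 differences were 4.35 for Muc16, -3.20 for Dbh and -6.58 for Krt5. With urethral replicate 1 left out, the log2 difference was -3.38 for Krt5. List calls ended for endothelial genes without bladder replicate 2 (camera adjusted p = 0.0843) and epithelial genes without bladder replicate 3 or urethral replicate 1 (adjusted p = 0.107 to 0.116). The list call arose for skeletal muscle genes without urethral replicates 2 or 3 (camera adjusted p = 0.00613 to 0.0182).

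The same comparison at E18.5 addressed the same aim later in development. Bladder mesenchyme was higher in called smooth muscle (19 of 20 tested), mesothelial (6 of 8) and epithelial genes (9 of 22, 1 opposite), and urethral mesenchyme in called skeletal muscle (14 of 20, 3 opposite) and neuronal genes (13 of 14) and patterning transcription factors (17 of 35, 6 opposite). No list call held with the estimated correlation. P2rx1, the ATP-gated channel of bladder muscle, was higher in bladder (444 ± 170.1 against 2.76 ± 0.781 CPM, log2 difference 7.32 ± 0.41, adjusted p = 7.9e-07), as were Plin4, a lipid droplet protein (log2 difference 7.36 ± 0.95, adjusted p = 0.00043), the neuropeptide Y receptor Npy6r (log2 difference 7.32 ± 0.95, adjusted p = 0.000182) and C3, a complement protein (log2 difference 6.56 ± 0.37, adjusted p = 8.01e-07). The myogenic regulators Myod1 (0.0571 ± 0.05396 against 40.3 ± 7.89 CPM, log2 difference -9.47 ± 1.21, adjusted p = 0.000153) and Myog (log2 difference -8.73 ± 1.17, adjusted p = 0.000242) were higher in urethral mesenchyme. Adcyap1, the precursor of the neuropeptide PACAP, Crnn, a protein of squamous epithelium, and the transcription factor Pax9 had no counts in the E18.5 bladder libraries and were at least 223-fold, at least 221-fold and at least 247-fold higher in urethral mesenchyme, taking 3 counts over the group as the floor. With limma-voom, the call of Adcyap1 ended (adjusted p = 0.0628). Of 18805 genes tested, 3482 were higher in bladder and 3053 in urethral mesenchyme, of which 1617 and 2067 differed at least 2-fold. P2rx1 lies on chromosome 11 from 72999103 to 73015200 and Myod1 on chromosome 7 from 46376474 to 46379099 of GRCm38. The log2 difference was -8.13 for Myog without bladder replicate 1. Without bladder replicate 2, Myod1 differed 1447-fold instead of 959.7-fold (counting interval 400.2 to 11949). With bladder replicate 3 left out, the log2 difference was -10.34 for Myog. Adcyap1 differed at least 365-fold without urethral replicate 1. Without urethral replicate 2, the log2 difference was 8.34 for Npy6r, and Crnn differed at least 141-fold. Folds here are ratios of summed counts.

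**Figure D2:**
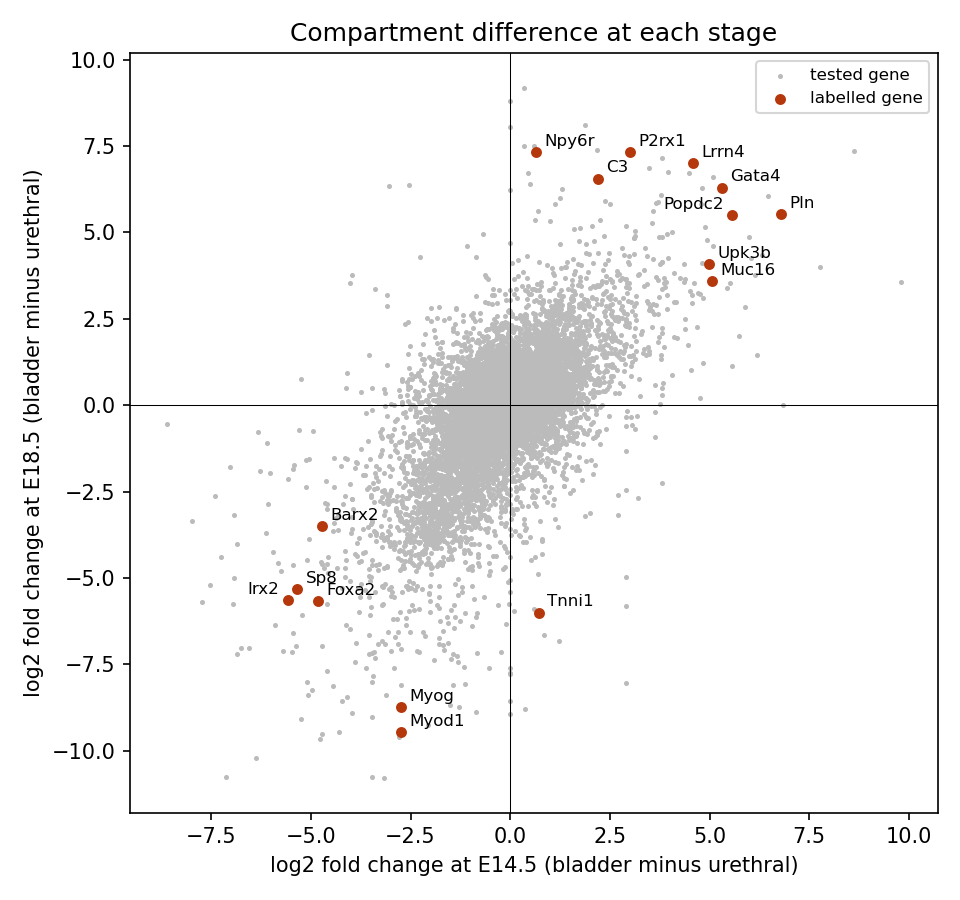
Each gray point is 1 of 18805 tested genes, with its log2 fold change between bladder and urethral mesenchyme at E14.5 on the x axis and at E18.5 on the y axis, and fitted values of genes without counts in a group depend on the prior count. Red points are named genes, of which P2rx1 sits at 3.00 and 7.32 and Irx2 at -5.58 on the x axis.

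Of contractile smooth muscle genes at E18.5, 19 of 20 tested members were higher in bladder and 0 higher in urethral mesenchyme (20 and 0 within the list, camera adjusted p = 1.3e-14, 0.286 with estimated correlation). Synm, an intermediate filament protein (1461 ± 566 against 19.1 ± 8.78 CPM, log2 difference 6.26 ± 0.80, adjusted p = 0.000172), and the smooth muscle actin Actg2 (5986 ± 2115 against 221 ± 36.3 CPM, log2 difference 4.76 ± 0.36, adjusted p = 3.76e-06) were among them. Of receptors and channels of bladder muscle, 9 of 17 tested members were higher in bladder and 1 higher in urethral mesenchyme (9 and 1 within the list, camera adjusted p = 0.0055, 0.356 with estimated correlation). An example was the tachykinin receptor Tacr2 (log2 difference 5.63 ± 0.64, adjusted p = 4.02e-05). Skeletal muscle genes parted. Of 20 tested members, 3 were higher in bladder and 14 higher in urethral mesenchyme (3 and 14 within the list, camera adjusted p = 1.64e-05, 0.505 with estimated correlation). Acta1, Ckm and Tnnt3, named after their values were seen, made up the members higher in bladder, and Ttn (0.271 ± 0.157 against 78.8 ± 33.7 CPM, log2 difference -8.10 ± 1.27, adjusted p = 0.000604) was among those higher in urethral mesenchyme. Leaving out any 1 E18.5 library ended the call of Acta1 (adjusted p = 0.0537 to 0.103), and any 1 E18.5 urethral library that of Ckm (adjusted p = 0.0661 to 0.0708). The log2 differences in these fits were 4.02 to 4.32 for Acta1 and 3.99 to 4.18 for Ckm. Both calls stood when only the 6 E18.5 libraries were fitted, and when replicate 1 of both E14.5 groups was left out. Of collagens, 8 of 16 tested members were higher in bladder and 2 higher in urethral mesenchyme (8 and 2 within the list, camera adjusted p = 0.0383, 0.686 with estimated correlation). An example was Col15a1 (log2 difference 1.37 ± 0.27, adjusted p = 0.00207). With replicate number as a block, the collagen call ended (camera adjusted p = 0.0842). Of elastic fibre and proteoglycan genes, 5 of 25 tested members were higher in bladder and 4 higher in urethral mesenchyme (6 and 4 within the list, camera adjusted p = 0.698). An example was Fn1 (log2 difference 1.41 ± 0.25, adjusted p = 0.000832). Of cell division genes, 11 of 24 tested members were higher in bladder and 0 higher in urethral mesenchyme (11 and 0 within the list, camera adjusted p = 0.0111, 0.686 with estimated correlation). An example was Mki67 (333 ± 57.8 against 180.2 ± 30.8 CPM, log2 difference 0.89 ± 0.18, adjusted p = 0.0025). With bladder replicate 3 left out, the log2 difference was -8.76 for Ttn. The log2 difference was 6.26 for Tacr2 without urethral replicate 2. The list call ended for collagen genes without bladder replicate 1 or urethral replicates 2 or 3 (camera adjusted p = 0.067 to 0.119).

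Patterning and hormone genes again differed. Of posterior Hox genes, 0 of 14 tested members were higher in bladder and 8 higher in urethral mesenchyme (1 and 8 within the list, camera adjusted p = 0.00448, 0.356 with estimated correlation). An example was Hoxd13 (24.8 ± 1.96 against 105 ± 11.6 CPM, log2 difference -2.09 ± 0.14, adjusted p = 1.26e-06). Of anterior Hox genes, 1 of 22 tested members were higher in bladder and 1 higher in urethral mesenchyme (1 and 0 within the list, camera adjusted p = 0.591). Of patterning transcription factors, 6 of 35 tested members were higher in bladder and 17 higher in urethral mesenchyme (7 and 17 within the list, camera adjusted p = 0.00448, 0.286 with estimated correlation). Six2 (0.682 ± 0.1895 against 39.7 ± 7.09 CPM, log2 difference -5.84 ± 0.37, adjusted p = 1.08e-06) and Eya1 (log2 difference -3.96 ± 0.44, adjusted p = 6.9e-05) were higher in urethral mesenchyme. Of retinoic acid genes, 1 of 14 tested members were higher in bladder and 11 higher in urethral mesenchyme (1 and 11 within the list, camera adjusted p = 1.49e-05, 0.222 with estimated correlation). Examples were Crabp2 (3.03 ± 0.495 against 44.9 ± 5.17 CPM, log2 difference -3.89 ± 0.17, adjusted p = 1.29e-07) and Aldh1a3, which makes retinoic acid (log2 difference -4.01 ± 0.30, adjusted p = 2.91e-06). Of sex steroid genes, 2 of 11 tested members were higher in bladder and 7 higher in urethral mesenchyme (2 and 7 within the list, camera adjusted p = 0.0243, 0.369 with estimated correlation). Srd5a2, which converts testosterone to dihydrotestosterone, was 366-fold (95% counting interval 125 to 1779.5) higher in urethral mesenchyme. Of Hedgehog targets, 0 of 7 tested members were higher in bladder and 1 higher in urethral mesenchyme (0 and 1 within the list, camera adjusted p = 0.301). An example was Foxf2 (log2 difference -2.34 ± 0.26, adjusted p = 3.87e-05). Of secreted Wnt antagonists, 0 of 11 tested members were higher in bladder and 6 higher in urethral mesenchyme (0 and 6 within the list, camera adjusted p = 0.0111, 0.286 with estimated correlation). An example was Dkk2 (24.1 ± 2.81 against 219 ± 15.7 CPM, log2 difference -3.18 ± 0.52, adjusted p = 0.000795). Of Wnt and R-spondin ligands, 3 of 18 tested members were higher in bladder and 6 higher in urethral mesenchyme (4 and 6 within the list, camera adjusted p = 0.964). Rspo1 (log2 difference 3.45 ± 0.42, adjusted p = 7.26e-05) was higher in bladder and Rspo2 (log2 difference -4.72 ± 0.55, adjusted p = 7.62e-05) in urethral mesenchyme. Of TGF-beta genes, 1 of 14 tested members were higher in bladder and 8 higher in urethral mesenchyme (1 and 9 within the list, camera adjusted p = 0.0111, 0.489 with estimated correlation). An example was Inhba (log2 difference -3.95 ± 0.42, adjusted p = 4.86e-05). Without bladder replicate 1, Srd5a2 differed at least 232-fold. With bladder replicate 3 left out, Srd5a2 differed 224-fold (counting interval 76.6 to 1090.1).

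Other cell type markers at E18.5 followed. Of neuronal genes, 0 of 14 tested members were higher in bladder and 13 higher in urethral mesenchyme (0 and 13 within the list, camera adjusted p = 2.92e-08, 0.356 with estimated correlation). An example was Th, the first enzyme of catecholamine synthesis (1.71 ± 0.7099 against 43.2 ± 11.8 CPM, log2 difference -4.64 ± 0.50, adjusted p = 3.46e-05). Of glial genes, 0 of 10 tested members were higher in bladder and 6 higher in urethral mesenchyme (0 and 6 within the list, camera adjusted p = 0.0186, 0.612 with estimated correlation). Of mesothelial genes, 6 of 8 tested members were higher in bladder and 0 higher in urethral mesenchyme (8 and 0 within the list, camera adjusted p = 0.000358, 0.356 with estimated correlation). An example was Lrrn4 (113 ± 20.7 against 0.906 ± 0.652 CPM, adjusted p = 6.51e-05). The summed level of epithelial genes was 13513 ± 1927 CPM in bladder and 5476 ± 1112 in urethral mesenchyme, and 9 of 22 tested members were higher in bladder and 1 higher in urethral mesenchyme (9 and 1 within the list, camera adjusted p = 0.016, 0.69 with estimated correlation). Upk2, a uroplakin of the bladder lining, was higher in bladder (595 ± 80.9 against 69.2 ± 27.4 CPM, log2 difference 3.11 ± 0.66, adjusted p = 0.00376) and the keratin Krt17 in urethral mesenchyme (3.33 ± 1.38 against 123 ± 38.7 CPM, log2 difference -5.23 ± 0.57, adjusted p = 6.37e-05). Of endothelial genes, 0 of 15 tested members were higher in bladder and 6 higher in urethral mesenchyme (0 and 6 within the list, camera adjusted p = 0.00827, 0.613 with estimated correlation). An example was Emcn (log2 difference -0.99 ± 0.23, adjusted p = 0.00444). Of pericyte and interstitial genes, 3 of 10 tested members were higher in bladder and 6 higher in urethral mesenchyme (3 and 6 within the list, camera adjusted p = 0.213). An example was Kit (log2 difference -1.90 ± 0.28, adjusted p = 0.00032). No leave-one-out fit moved the E18.5 counts of called genes by over 1.5 times. The log2 difference was 7.67 for Lrrn4 without urethral replicate 3.

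**Figure D3:**
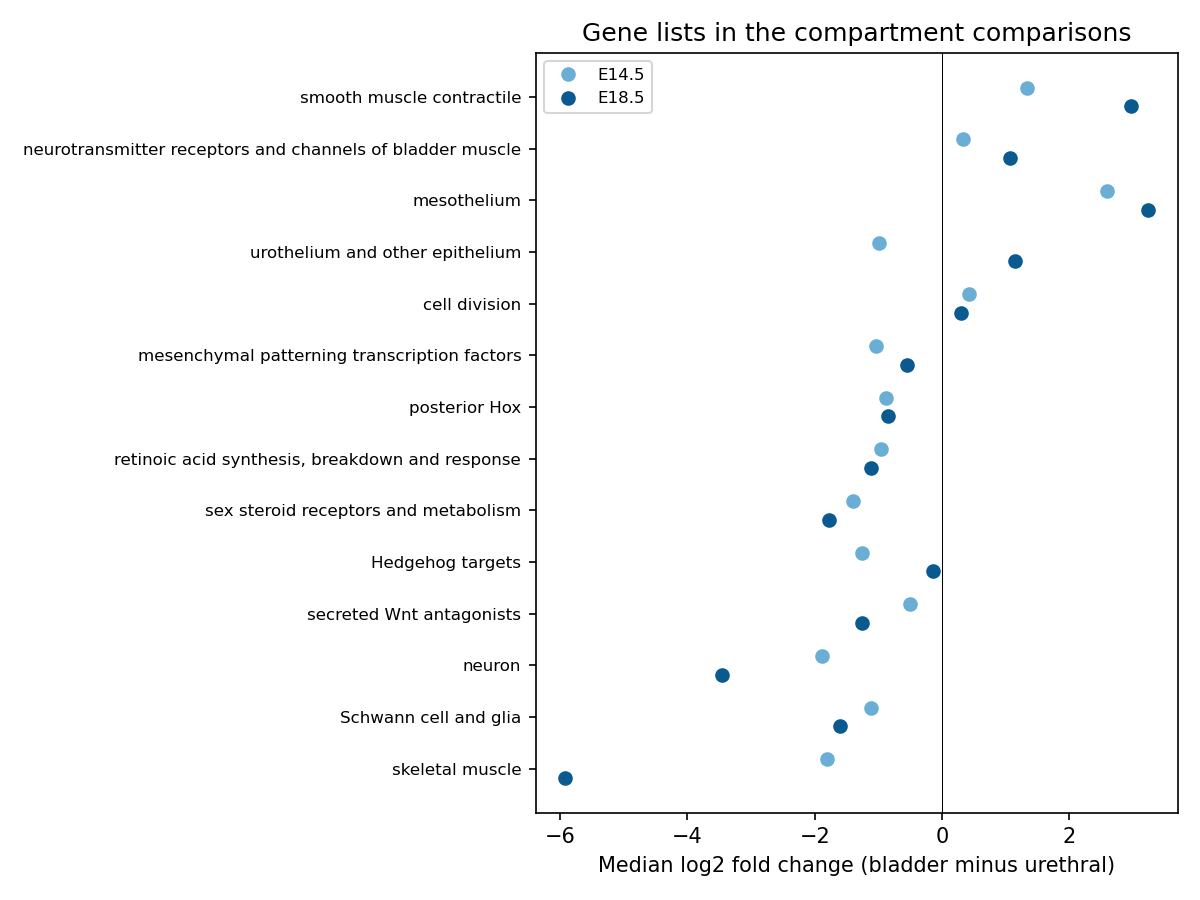
Median log2 fold change between bladder and urethral mesenchyme (x axis) over the tested genes of 14 of the 36 gene lists, fixed in advance but picked for display after the results, at E14.5 (light points) and E18.5 (dark points). Smooth muscle genes lie at 1.34 and 2.97, neuronal genes at -1.89 and -3.46, skeletal muscle genes at -1.80 at E14.5 and sex steroid genes at -1.40 and -1.77, the last 3 also with genes that have a group at or under 3 counts at their bound or counted ratio.

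Much of the compartment difference was shared between stages. Hoxd13, Six2, Foxf2, Rspo2 and Nog were higher in urethral mesenchyme at both stages, and P2rx1, Kcnmb1, Upk3b and Muc16 in bladder. In all, 1324 genes were higher in bladder at both stages, where independent lists would share 432, and 1427 were higher in urethral mesenchyme at both, where independent lists would share 380.2. Another 52 genes were higher in bladder at E14.5 and in urethral mesenchyme at E18.5, and 85 the reverse. Across genes, which are not independent replicates, Pearson's r between the log2 differences was 0.625. Requiring at least a 2-fold difference left 522 and 918 shared genes. At E18.5, Nog (log2 difference -2.87 ± 0.31, adjusted p = 2.68e-05), Kcnmb1 (log2 difference 4.33 ± 0.25, adjusted p = 7.31e-07), Upk3b (log2 difference 4.09 ± 0.56, adjusted p = 0.000272) and Muc16 (log2 difference 3.60 ± 0.64, adjusted p = 0.00133) had these differences, and P2rx1 at E14.5 (log2 difference 3.00 ± 0.43, adjusted p = 0.000718).

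The change of the compartment difference between the stages was tested directly. It moved towards bladder for called smooth muscle (13 of 20 tested) and epithelial genes (5 of 22), and towards urethral mesenchyme for called skeletal muscle genes (6 of 20, 1 opposite), Wnt antagonists (3 of 11) and endothelial genes (6 of 15). With the estimated correlation, no list call held. Thrsp moved towards bladder (log2 change of the difference 6.54 ± 0.89, adjusted p = 0.00184), as did the glutamate transporter Slc1a1 (log2 change of the difference 4.99 ± 0.69, adjusted p = 0.00209). Opposite-strand exons cover 31.9% of those of Slc1a1, so its level is uncertain too. Npy6r had 0.239 ± 0.229 and 0.1299 ± 0.164 CPM in bladder and urethral mesenchyme at E14.5, 45.9 ± 25.4 and 0.313 ± 0.3102 at E18.5 (log2 change of the difference 6.67 ± 1.76, adjusted p = 0.0405). Hdc, which makes histamine, moved towards bladder as its urethral level fell (log2 change of the difference 5.00 ± 1.14, adjusted p = 0.0231). The slow muscle troponin Tnni1 had 9.03 ± 1.27 and 5.498 ± 4.28 CPM in bladder and urethral mesenchyme at E14.5, 1.11 ± 0.156 and 70.3 ± 12.3 at E18.5 (log2 change of the difference -6.72 ± 0.63, adjusted p = 0.000673), and Myod1 (log2 change of the difference -6.72 ± 1.59, adjusted p = 0.0247) and myostatin, Mstn (log2 change of the difference -6.51 ± 0.97, adjusted p = 0.00268), also moved towards urethral mesenchyme. Of 18805 genes tested, 873 moved towards bladder and 758 towards urethral mesenchyme, 561 and 575 of them at least 2-fold. With 1 library left out, calls ended for Npy6r without E14.5 bladder replicates 2 or 3 or E14.5 urethral replicates 1 or 2 or E18.5 bladder replicates 1 or 2 or E18.5 urethral replicates 1 or 3 (adjusted p = 0.0591 to 0.465), Hdc without E14.5 bladder replicate 2 or E14.5 urethral replicate 3 or E18.5 bladder replicate 3 or E18.5 urethral replicates 1 or 2 (adjusted p = 0.0514 to 0.0655) and Myod1 without E14.5 bladder replicates 2 or 3 or E18.5 bladder replicates 1 or 3 (adjusted p = 0.0543 to 0.0768). With replicate number as a block, the call of Hdc ended (adjusted p = 0.0511), and limma-voom ended those of Hdc (adjusted p = 0.0643) and Npy6r (adjusted p = 0.176). Without E14.5 bladder replicate 1, log2 changes were 7.56 for Npy6r and 6.07 for Hdc, and Thrsp kept 2 counts in that group. With E14.5 bladder replicate 2 left out, log2 changes were 5.95 for Thrsp and 6.08 for Npy6r. Log2 changes were -7.56 for Tnni1, -8.59 for Myod1 and -7.36 for Mstn without E14.5 urethral replicate 1. Without E14.5 urethral replicate 2, Npy6r kept 2 counts in that group, as did Mstn without E18.5 bladder replicate 3. The log2 change was 7.68 for Npy6r without E18.5 urethral replicate 2.

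Of smooth muscle genes, 13 of 20 tested members moved towards bladder and 0 towards urethral mesenchyme (17 and 0 within the list, camera adjusted p = 1.13e-10, 0.521 with estimated correlation). Examples were Synm (log2 change of the difference 4.96 ± 0.98, adjusted p = 0.0124) and Actg2 (log2 change of the difference 3.04 ± 0.44, adjusted p = 0.00291). Of receptors and channels of bladder muscle, 5 of 17 tested members moved towards bladder and 0 towards urethral mesenchyme (7 and 2 within the list, camera adjusted p = 0.0182, 0.521 with estimated correlation). An example was P2rx1 (log2 change of the difference 4.33 ± 0.59, adjusted p = 0.00237). Of epithelial genes, 5 of 22 tested members moved towards bladder and 0 towards urethral mesenchyme (8 and 1 within the list, camera adjusted p = 3.04e-06, 0.584 with estimated correlation). An example was Trp63, a regulator of basal epithelium (log2 change of the difference 3.32 ± 0.72, adjusted p = 0.0183). Of skeletal muscle genes, 1 of 20 tested members moved towards bladder and 6 towards urethral mesenchyme (1 and 9 within the list, camera adjusted p = 3.28e-06, 0.584 with estimated correlation). Of endothelial genes, 0 of 15 tested members moved towards bladder and 6 towards urethral mesenchyme (0 and 10 within the list, camera adjusted p = 1.46e-06, 0.521 with estimated correlation). An example was Tek (log2 change of the difference -1.78 ± 0.32, adjusted p = 0.00651). Of secreted Wnt antagonists, 0 of 11 tested members moved towards bladder and 3 towards urethral mesenchyme (1 and 7 within the list, camera adjusted p = 0.00378, 0.347 with estimated correlation). Sfrp1 had 264 ± 22.3 and 135 ± 23.4 CPM in bladder and urethral mesenchyme at E14.5, 78.5 ± 5.93 and 193 ± 45.7 at E18.5 (log2 change of the difference -2.27 ± 0.24, adjusted p = 0.000773). Of retinoic acid genes, 2 of 14 tested members moved towards bladder and 5 towards urethral mesenchyme (2 and 6 within the list, camera adjusted p = 0.0311, 0.521 with estimated correlation). Aldh1a3 moved towards urethral mesenchyme (log2 change of the difference -3.23 ± 0.40, adjusted p = 0.00123) and Aldh1a1 towards bladder (log2 change of the difference 3.21 ± 0.62, adjusted p = 0.00982). With replicate number as a block, the call of the retinoic acid list ended (camera adjusted p = 0.0559). Of leukocyte genes, 0 of 13 tested members moved towards bladder and 3 towards urethral mesenchyme (0 and 7 within the list, camera adjusted p = 0.000114, 0.521 with estimated correlation). Of neuronal genes, 0 of 14 tested members moved towards bladder and 2 towards urethral mesenchyme (0 and 2 within the list, camera adjusted p = 0.00121, 0.584 with estimated correlation). Of elastic fibre and proteoglycan genes, 1 of 25 tested members moved towards bladder and 3 towards urethral mesenchyme (1 and 5 within the list, camera adjusted p = 0.0435, 0.685 with estimated correlation). Of anterior Hox genes, 1 of 22 tested members moved towards bladder and 0 towards urethral mesenchyme (1 and 0 within the list, camera adjusted p = 0.0311, 0.685 with estimated correlation). The BMP antagonist Fst moved towards urethral mesenchyme (log2 change of the difference -3.43 ± 0.48, adjusted p = 0.00237) and the ligand Bmp7 towards bladder (log2 change of the difference 1.56 ± 0.28, adjusted p = 0.00651). With 1 library left out, calls ended for Trp63 without E18.5 bladder replicate 1 or urethral replicates 1 or 2 (adjusted p = 0.0513 to 0.0572). Replicate 1 carries the E14.5 summed levels of skeletal muscle genes in both compartments and of epithelial genes in bladder, which were 34.03, 36.01 and 447 CPM without it. Counts of genes moving towards bladder were 1505 without E14.5 bladder replicate 1, 502 and 577 without replicate 3 of E14.5 bladder or urethral mesenchyme, 546 without E18.5 bladder replicate 1, and 504, 519 and 543 without E18.5 urethral replicates 1, 2 and 3. Those towards urethral mesenchyme were 497, 493, 483 and 470 without E14.5 bladder replicate 3, E14.5 urethral replicate 3, and E18.5 urethral replicates 2 and 3. Without E14.5 bladder replicate 1, log2 changes were 6.27 for Synm and 4.30 for Trp63. List calls ended for elastic fibre genes without E14.5 bladder replicate 1 or E14.5 urethral replicates 2 or 3 or E18.5 bladder replicate 3 or E18.5 urethral replicate 1 (camera adjusted p = 0.0682 to 0.259), receptor and channel genes without E14.5 bladder replicate 1 or E14.5 urethral replicate 2 or E18.5 bladder replicate 1 (adjusted p = 0.0514 to 0.0943), anterior Hox genes without E14.5 bladder replicate 2 or E14.5 urethral replicate 2 or E18.5 bladder replicate 3 (adjusted p = 0.0789 to 0.152) and retinoic acid genes without E14.5 urethral replicate 2 or E18.5 urethral replicate 1 (adjusted p = 0.0562 to 0.108).

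**Figure D4:**
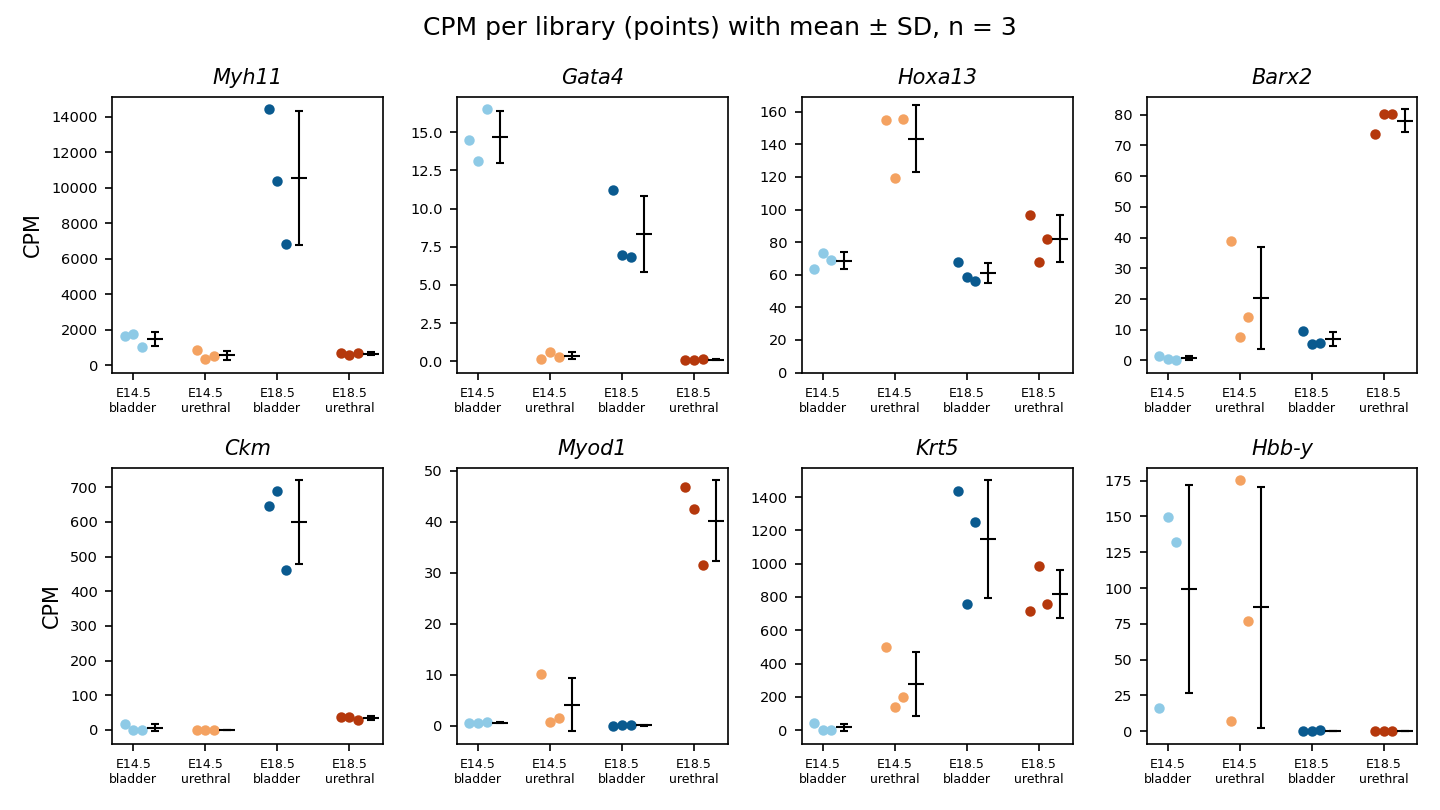
CPM of 8 genes (y axis, 1 panel per gene) in the 4 groups (x axis), 1 point per library with the group mean and SD beside it. Myod1 reached 40.3 ± 7.89 CPM in E18.5 urethral mesenchyme and Hbb-y fell from 99.4 ± 72.6 to 0.2599 ± 0.2498 CPM in bladder.

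From E14.5 to E18.5 in bladder mesenchyme, most smooth muscle, epithelial and collagen genes rose and most cell division and erythroid genes fell. The stages lie in separate tables from separate litters. The labels name no batch, but within 1 compartment a difference between tables cannot be told apart from stage. Where alike in both compartments it cancels in the direct test of the change, which called 13 of 20 smooth muscle genes. C3 (528 ± 143 against 1.18 ± 0.681 CPM, log2 change 8.82 ± 0.43, adjusted p = 1.18e-06) and Npy6r (log2 change 7.59 ± 0.99, adjusted p = 0.000149) rose. The embryonic globins Hbb-y (0.2599 ± 0.2498 against 99.4 ± 72.6 CPM, log2 change -8.44 ± 1.46, adjusted p = 0.000857), Hba-x (log2 change -6.51 ± 1.09, adjusted p = 0.000668) and the cartilage collagen Col2a1 (log2 change -4.90 ± 0.68, adjusted p = 0.000161) fell. Of 18805 genes tested, 4461 rose and 4136 fell, 2765 and 1519 of them at least 2-fold. Of smooth muscle genes, 19 of 20 tested members were higher at E18.5 and 0 lower (19 and 0 within the list, camera adjusted p = 4.41e-08, 0.419 with estimated correlation). An example was Myh11, the smooth muscle myosin (10548 ± 3799.5 against 1466 ± 396 CPM, log2 change 2.85 ± 0.37, adjusted p = 0.000105). Of skeletal muscle genes, 7 of 20 tested members were higher at E18.5 and 0 lower (7 and 0 within the list, camera adjusted p = 0.192). Examples were Ckm (log2 change 6.70 ± 1.32, adjusted p = 0.00194) and Tnnt3 (log2 change 6.17 ± 0.46, adjusted p = 8.65e-06). Of collagens, 13 of 16 tested members were higher at E18.5 and 1 lower (13 and 1 within the list, camera adjusted p = 0.00297, 0.674 with estimated correlation). An example was Col6a3 (log2 change 1.71 ± 0.25, adjusted p = 0.000181). Elastic fibre and proteoglycan genes went both ways, and 10 of 25 tested members were higher at E18.5 and 5 lower (10 and 5 within the list, camera adjusted p = 0.23). Of cell division genes, 0 of 24 tested members were higher at E18.5 and 22 lower (0 and 22 within the list, camera adjusted p = 3.26e-09, 0.419 with estimated correlation). An example was Mcm5, a replication helicase subunit (log2 change -1.51 ± 0.15, adjusted p = 1.91e-05). Of epithelial genes, 21 of 22 tested members were higher at E18.5 and 0 lower (21 and 0 within the list, camera adjusted p = 1.96e-09, 0.452 with estimated correlation). An example was Krt5 (1148 ± 353 against 16.2 ± 22.97 CPM, log2 change 6.15 ± 1.08, adjusted p = 0.00095). Without replicate 1, E14.5 means were 2.92 CPM for Krt5, 447 CPM for the epithelial sum, 34.03 CPM for the skeletal muscle sum and 0.0829 CPM for Ckm. Of retinoic acid genes, 3 of 14 tested members were higher at E18.5 and 10 lower (3 and 10 within the list, camera adjusted p = 0.00643, 0.419 with estimated correlation). An example was Stra6 (log2 change -3.97 ± 0.43, adjusted p = 4.71e-05). Of erythroid genes, 0 of 9 tested members were higher at E18.5 and 9 lower (0 and 9 within the list, camera adjusted p = 0.00196, 0.419 with estimated correlation). Of leukocyte genes, 5 of 13 tested members were higher at E18.5 and 0 lower (5 and 0 within the list, camera adjusted p = 0.0274, 0.62 with estimated correlation). Of Hedgehog targets, 1 of 7 tested members were higher at E18.5 and 5 lower (1 and 5 within the list, camera adjusted p = 0.116). With limma-voom, the call of Hbb-y ended (adjusted p = 0.107). With E14.5 bladder replicate 1 left out, log2 changes were 8.45 for Npy6r, 12.73 for Ckm and 8.62 for Krt5. The log2 change was 6.99 for Npy6r without E14.5 bladder replicate 2. Without E14.5 bladder replicate 3, the log2 change was 6.11 for Ckm. With E18.5 bladder replicate 2 left out, the log2 change was -4.74 for Stra6. The log2 change was -9.75 for Hbb-y without E18.5 bladder replicate 3. The list call ended for leukocyte genes without E18.5 bladder replicate 2 (camera adjusted p = 0.0805). The list call arose for Hedgehog target genes without E14.5 bladder replicate 1 (camera adjusted p = 0.0395).

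The same stages in urethral mesenchyme, with the same limit, showed most skeletal muscle, leukocyte and collagen genes rising and most cell division genes and Hedgehog targets falling. Krt13, a keratin of stratified epithelium, rose (216 ± 74.8 against 0.297 ± 0.241 CPM, log2 change 9.58 ± 0.50, adjusted p = 9.65e-06). Mroh4, with no counts at E14.5, was at least 197-fold higher at E18.5. Hbb-y (log2 change -9.03 ± 1.51, adjusted p = 0.00239), Hba-x (log2 change -7.04 ± 1.12, adjusted p = 0.00175), the prokineticin receptor Prokr2 (2.08 ± 0.795 against 52.8 ± 31.7 CPM, log2 change -4.64 ± 0.52, adjusted p = 0.000314) and Hdc (log2 change -4.01 ± 0.85, adjusted p = 0.00743) fell. Of 18805 genes tested, 2558 rose and 2028 fell, 1815 and 360 of them at least 2-fold. Of skeletal muscle genes, 20 of 20 tested members were higher at E18.5 and 0 lower (20 and 0 within the list, camera adjusted p = 3.15e-13, 0.308 with estimated correlation). An example was Ttn (78.8 ± 33.7 against 2.21 ± 3.46 CPM, log2 change 5.20 ± 1.03, adjusted p = 0.00546). Without replicate 1, E14.5 means were 0.212 CPM for Ttn and 36.01 CPM for the skeletal muscle sum. Of smooth muscle genes, 2 of 20 tested members were higher at E18.5 and 1 lower (1 and 1 within the list, camera adjusted p = 0.208). Of leukocyte genes, 13 of 13 tested members were higher at E18.5 and 0 lower (13 and 0 within the list, camera adjusted p = 4.03e-10, 0.28 with estimated correlation). An example was Lyz2, a lysozyme (log2 change 2.22 ± 0.28, adjusted p = 0.000404). Of collagens, 12 of 16 tested members were higher at E18.5 and 1 lower (14 and 1 within the list, camera adjusted p = 1e-06, 0.37 with estimated correlation). An example was Col12a1 (log2 change 1.48 ± 0.19, adjusted p = 0.00047). Of cell division genes, 0 of 24 tested members were higher at E18.5 and 23 lower (0 and 24 within the list, camera adjusted p = 1.22e-13, 0.308 with estimated correlation). An example was Rrm2 (log2 change -1.15 ± 0.14, adjusted p = 0.000342). Of Hedgehog targets, 0 of 7 tested members were higher at E18.5 and 6 lower (0 and 6 within the list, camera adjusted p = 0.000148, 0.308 with estimated correlation). Examples were Foxl1 (19.1 ± 6.44 against 87.4 ± 22.6 CPM, log2 change -2.19 ± 0.28, adjusted p = 0.000439) and Ptch1, the Hedgehog receptor (log2 change -1.29 ± 0.25, adjusted p = 0.00369). Of epithelial genes, 11 of 22 tested members were higher at E18.5 and 0 lower (15 and 0 within the list, camera adjusted p = 1.69e-06, 0.37 with estimated correlation). An example was Krt7 (log2 change 3.03 ± 0.49, adjusted p = 0.00199). With limma-voom, the call of Hbb-y ended (adjusted p = 0.174). The count of rising genes was 1461 without E14.5 urethral replicate 3 and 1705 without E18.5 urethral replicate 2. That of falling genes was 890 without E14.5 urethral replicate 3 and 1310, 1001 and 1004 without E18.5 urethral replicates 1, 2 and 3. Without E14.5 urethral replicate 1, log2 changes were 10.42 for Krt13 and 8.58 for Ttn. With E14.5 urethral replicate 2 left out, log2 changes were -7.99 for Hbb-y, -5.88 for Hba-x and 4.60 for Ttn. The log2 change was -10.05 for Hbb-y without E18.5 urethral replicate 3. The list call arose for smooth muscle genes without E14.5 urethral replicate 1 (camera adjusted p = 0.0178).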

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

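The tests of a litter further along, embryonic globins, striated muscle and the actin genes, and both of epithelium, were chosen only after the results were seen.

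The first weighed pattern is that replicate 1 of both E14.5 groups lay towards E18.5. Genes that rise from E14.5 to E18.5 had covered a median 0.3404 of that change in bladder replicate 1 and 0.361 in urethral replicate 1. More epithelium, muscle or other tissue in these samples does not account for their embryonic globins, which were at most 0.159 of the lower of the other replicates where dilution alone would leave at least 0.5. For the other falling genes that explanation cannot be told apart: the lower median share was 0.191 against 0.0859 and -0.0767 in the other bladder replicates (urethral 0.323 against 0.155 and -0.127), above the bound of 0.1 set beforehand but by less than the gap between those replicates, a rule on spread added after the values were seen. A litter further along in development may account for the pattern and stays open, since embryonic globins made up at most 1.59% of haemoglobin counts in replicate 1 against 10.96 to 20.4% in the other E14.5 libraries.

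The second pattern is that Acta1 (3166 ± 722 against 179 ± 13.03 CPM, log2 difference 4.14 ± 1.32, adjusted p = 0.0315), Ckm (599 ± 120.5 against 34.8 ± 5.13 CPM, log2 difference 4.10 ± 1.15, adjusted p = 0.0171) and Tnnt3 (log2 difference 2.69 ± 0.38, adjusted p = 0.00033), named after their values were seen, were higher in E18.5 bladder while Myod1, Myog and Ttn were higher in urethral mesenchyme. The differences held in size while calls were lost: that of Acta1 ended without any 1 of the 6 E18.5 libraries (adjusted p = 0.0537 to 0.103, log2 difference 4.02 to 4.32), that of Ckm without any 1 of the 3 E18.5 urethral libraries (adjusted p = 0.0661 to 0.0708, log2 difference 3.99 to 4.18), and both without the low-count filter (adjusted p = 0.105 and 0.0673). Striated muscle dissected into the bladder samples is argued against by the 17 other skeletal muscle genes, whose median log2 difference was -6.57 (SD 3.22). Reads shared between actin genes would keep the ratio of Acta1 to Acta2 plus Actg2 about constant, and its highest value was 103 times the lowest among the 6 bladder libraries, with 0.2800 to 6.08% at E14.5 (the highest in replicate 1) and 23.5 to 28.8% at E18.5: E18.5 urethral libraries had 13.1 to 17.6%, so E18.5 alone argues little and the argument rests on E14.5 and on Ckm and Tnnt3, which are no actins. Expression of these genes in bladder smooth muscle may account for the pattern as a hypothesis, and a compartment difference stays open, untested.

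The third pattern is that epithelial genes were abundant in mesenchyme libraries and differed between compartments at E18.5. A single kind of epithelium left on the bladder samples is argued against, since 8 of 22 genes lay over 2 standard errors from the list median of 1.14. Epithelium in amounts that differ between libraries stays open and may account for part of it. Deviations of these genes from group means correlated at a mean of 0.443 over 10 libraries, leaving out replicate 1 of both E14.5 groups. Among 10000 random lists the central 95% ended at 0.183 and the highest was 0.4297. Expression of these genes in mesenchyme was not tested, as no separated epithelium was analysed, and a compartment difference remains open.

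The called genes were set beside other groupings of libraries, with 10 splits of 3 against 3 per comparison, which allow no share under 0.1. For bladder against urethral mesenchyme, the real split gave 4677 at E14.5 and 6535 at E18.5, and any other at most 0. For the change of the difference, fitted with replicate number as a block, the real split gave 1894 and any other at most 0. Between stages, the real split gave 8597 in bladder and any other at most 1, and in urethral mesenchyme 4586 and at most 0. In each case only the real split of the 10 gave as many as the real count.

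The direct test of a difference between the stages singled out the following values. The bladder-urethra difference moved towards bladder for 873 genes and towards urethral mesenchyme for 758. The log2 change of the difference was 3.04 for Actg2, 3.21 for Aldh1a1, -3.23 for Aldh1a3, 1.56 for Bmp7, 4.37 for C3, -1.16 for Col12a1, 1.56 for Col15a1, -3.57 for Col9a3, -2.56 for Crabp2, -1.51 for Emcn, -3.43 for Fst, 5.00 for Hdc, -2.16 for Inhba, 1.35 for Kcnmb1, -2.46 for Kit, -4.89 for Krt13, -2.26 for Lgr5, -2.11 for Lyz2, -6.51 for Mstn, 2.62 for Myh11, -6.72 for Myod1, -6.00 for Myog, 6.67 for Npy6r, 4.33 for P2rx1, 3.15 for Rspo1, 1.95 for Sema3e, -2.27 for Sfrp1, -2.35 for Six2, 4.99 for Slc1a1, -2.79 for Sostdc1, -2.44 for Stra6, 4.96 for Synm, 4.94 for Tacr2, -1.78 for Tek, -2.80 for Th, 6.54 for Thrsp, -6.72 for Tnni1, 2.71 for Tnnt3 and 3.32 for Trp63. With a group at or under 3 counts, the adjusted p of the change was 0.04 for Pax2 and 0.0378 for Srd5a2. Median log2 changes over gene lists were 0.66 for anterior Hox (paralogue groups 1 to 8), -1.79 for cartilage and bone, -0.46 for elastic fibres and matrix proteoglycans, -0.89 for endothelium, -0.73 for macrophage and other leukocyte, -1.57 for neuron, 0.80 for neurotransmitter receptors and channels of bladder muscle, -0.70 for retinoic acid synthesis, breakdown and response, -2.04 for secreted Wnt antagonists, -3.28 for skeletal muscle, 1.56 for smooth muscle contractile and 1.65 for urothelium and other epithelium. With the 1 gene that has a group at or under that count at its counted ratio, groups at 0 raised to 3, the skeletal muscle median was -3.60, and the other lists named here held no such gene. Log2 changes were 7.56 for Npy6r, 6.07 for Hdc, 6.27 for Synm and 4.30 for Trp63, and Thrsp kept 2 counts in that group without E14.5 bladder replicate 1. Without E14.5 bladder replicate 2, log2 changes were 5.95 for Thrsp and 6.08 for Npy6r. With E14.5 urethral replicate 1 left out, log2 changes were -7.56 for Tnni1, -8.59 for Myod1 and -7.36 for Mstn. Npy6r kept 2 counts in that group without E14.5 urethral replicate 2, as did Mstn without E18.5 bladder replicate 3. The log2 change was 7.68 for Npy6r without E18.5 urethral replicate 2.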

How the results depend on the processing

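The only alternative chosen after seeing the data was leaving out replicate 1 of both E14.5 groups.

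The size of the difference at E14.5, its change between stages and the stage difference in urethral mesenchyme depended on single libraries. With each library left out in turn, 1403 to 2165 genes were higher in E14.5 bladder and 1261 to 2729 in E14.5 urethral mesenchyme. The difference then moved towards bladder for 502 to 1505 genes and towards urethral mesenchyme for 470 to 917, and in the same fits 1461 to 2698 genes rose and 890 to 1956 fell with stage in urethral mesenchyme. With only the 6 libraries compared, 1384 genes were higher in E14.5 bladder. DESeq2 moved the difference towards urethral mesenchyme for 1333 genes. Its share of false calls in the simulated sets, where only 200 genes were changed, does not carry over to this count. Without replicate 1 of both E14.5 groups, the difference moved towards bladder for 1450 genes. With at least a 2-fold difference required, 522 genes were higher in bladder and 918 in urethral mesenchyme at both stages. Counts at E18.5 and for the stages in bladder stayed within 1.5 times under each alternative run.

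With replicate number as a block, 2327 and 2468 genes were called at E14.5, 3476 and 3083 at E18.5, 1063 and 831 for the change of the difference, 4271 and 3901 between stages in bladder and 2418 and 1691 in urethral mesenchyme. At E14.5, column names and low embryonic globins in both replicate 1 libraries go with pairing. Same-numbered deviations correlated at 0.191, -0.0285, 0.206, and replicate 2 not best with its own number. The block ended the calls of Hdc (adjusted p = 0.0511) and of retinoic acid genes (adjusted p = 0.0559) for the change of the difference and of collagens at E18.5 (adjusted p = 0.0842), and added calls of Des and of FGF and Wnt ligands at E14.5 and of TGF-beta genes for the change. It changed no other call of a named gene, nor of a list in the compartment comparisons and their change; list tests between the stages were not run with it.

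Of 128 named gene results, none changed sign in an alternative fit that gave them an adjusted p. Use of limma-voom ended 5 calls, of Adcyap1 at E18.5 (0.0628), Npy6r for the change (0.176), Hdc for the change (0.0643), Hbb-y between stages in bladder (0.107) and Hbb-y between stages in urethral mesenchyme (0.174), with adjusted p in parentheses. No low-count filter ended 6, of Npy6r for the change (0.124), Hdc for the change (0.0763), Myod1 for the change (0.0813), Trp63 for the change (0.0637), Acta1 at E18.5 (0.105) and Ckm at E18.5 (0.0673). Median-ratio size factors ended 0 and DESeq2 0, and 29 results from fits with 1 library left out lost a call and 1 gained one. Of 76 list calls, the estimated correlation ended 76, fry 13, the stricter filter 2 and leaving out replicate 1 of both E14.5 groups 5, while the last 3 added 18, 4 and 19. Fits with 1 library left out ended list calls in 56 cases and added them in 41. List results therefore depend on the preset correlation.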

Other observations

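Further gene groups not yet described also held called genes in some comparisons. Of 5 tested adipocyte genes, 3 rose and 0 fell in bladder (3 and 0 within the list, camera adjusted p = 0.0326, 0.419 with estimated correlation), and 3 rose and 0 fell in urethral mesenchyme (3 and 0 within the list, camera adjusted p = 0.00273, 0.308 with estimated correlation). An example was Fabp4 at 10.96 ± 5.35 CPM in E14.5 and 402 ± 182 CPM in E18.5 bladder (log2 change 5.20 ± 0.65, adjusted p = 0.000122). Between compartments, 3 of 5 tested members were higher in bladder and 0 higher in urethral mesenchyme (3 and 0 within the list, camera adjusted p = 0.159) at E14.5 and 2 of 5 tested members were higher in bladder and 0 higher in urethral mesenchyme (2 and 0 within the list, camera adjusted p = 0.213) at E18.5. Of cartilage and bone genes at E18.5, 0 of 9 tested members were higher in bladder and 5 higher in urethral mesenchyme (0 and 5 within the list, camera adjusted p = 0.0111, 0.378 with estimated correlation). An example was Col9a3 (3.37 ± 0.9701 against 25.8 ± 7.85 CPM, log2 difference -2.93 ± 0.31, adjusted p = 2.34e-05). At E14.5, 1 of 9 tested members were higher in bladder and 5 higher in urethral mesenchyme (3 and 5 within the list, camera adjusted p = 0.253), and between the stages 0 of 9 tested members moved towards bladder and 3 towards urethral mesenchyme (0 and 5 within the list, camera adjusted p = 0.0311, 0.584 with estimated correlation). Of immediate early and stress genes, which tissue handling can induce, in bladder and then urethral mesenchyme 9 of 15 tested members were higher at E18.5 and 1 lower (9 and 1 within the list, camera adjusted p = 0.00289, 0.62 with estimated correlation), and 12 of 15 tested members were higher at E18.5 and 0 lower (12 and 0 within the list, camera adjusted p = 7.39e-06, 0.37 with estimated correlation). An example was Fos (log2 change 3.08 ± 0.44, adjusted p = 0.000173) in bladder. Between compartments, 3 of 15 tested members were higher in bladder and 2 higher in urethral mesenchyme at each stage. Within the list, 4 and 2 were called (camera adjusted p = 0.744 at E14.5 and 0.964 at E18.5). Of Mullerian and Wolffian duct genes, 1 of 7 tested members were higher in bladder and 0 higher in urethral mesenchyme (1 and 0 within the list, camera adjusted p = 0.217) at E18.5, and Pax2, with no counts in E18.5 urethral mesenchyme, had 0.467 ± 0.216 CPM in bladder, at least 12.4-fold higher.

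Of FGF ligands at E18.5, 0 of 12 tested members were higher in bladder and 4 higher in urethral mesenchyme (1 and 4 within the list, camera adjusted p = 0.13). An example was Fgf10 (log2 difference -1.42 ± 0.32, adjusted p = 0.00412). Of FGF and ERK targets, 0 of 10 tested members were higher in bladder and 3 higher in urethral mesenchyme (0 and 3 within the list, camera adjusted p = 0.139). An example was Etv4 (log2 difference -2.88 ± 0.36, adjusted p = 7.3e-05). Of BMP targets at E18.5, 3 of 9 tested members were higher in bladder and 2 higher in urethral mesenchyme (3 and 2 within the list, camera adjusted p = 0.964). Of BMP and GDF ligands, 4 of 13 tested members were higher in bladder and 4 higher in urethral mesenchyme (4 and 4 within the list, camera adjusted p = 0.788). An example was Bmp3 (340.2 ± 49.9 against 91.6 ± 31.2 CPM, log2 difference 1.89 ± 0.38, adjusted p = 0.00256). Of secreted BMP antagonists, 2 of 11 tested members were higher in bladder and 4 higher in urethral mesenchyme (2 and 5 within the list, camera adjusted p = 0.119). An example was Grem1 (log2 difference -5.34 ± 0.64, adjusted p = 5.55e-05). Of canonical Wnt targets at E18.5, 3 of 13 tested members were higher in bladder and 5 higher in urethral mesenchyme (4 and 5 within the list, camera adjusted p = 0.657). An example was Lgr5 (1.83 ± 0.245 against 28.1 ± 4.24 CPM, log2 difference -3.93 ± 0.40, adjusted p = 1.99e-05). Of neurotrophic and axon guidance genes at E18.5, 6 of 20 tested members were higher in bladder and 6 higher in urethral mesenchyme (8 and 6 within the list, camera adjusted p = 0.842). Examples were Gdnf (log2 difference -3.81 ± 0.61, adjusted p = 0.000401) and Sema3e (log2 difference 1.85 ± 0.20, adjusted p = 3.31e-05). Of leukocyte genes at E14.5, 5 of 13 tested members were higher in bladder and 0 higher in urethral mesenchyme (5 and 0 within the list, camera adjusted p = 0.000935, 0.431 with estimated correlation). An example was Mrc1 (64.99 ± 15.2 against 19.7 ± 4.57 CPM, log2 difference 1.72 ± 0.21, adjusted p = 0.000243). Of erythroid genes at E14.5, 4 of 9 tested members were higher in bladder and 0 higher in urethral mesenchyme (5 and 0 within the list, camera adjusted p = 0.0135, 0.431 with estimated correlation). Without E14.5 bladder replicate 1, the log2 change was 3.84 for Fos. With E18.5 bladder replicate 1 left out, the log2 difference was -4.78 for Gdnf. List calls ended for cartilage genes between the stages without E14.5 bladder replicates 1 or 2 or E14.5 urethral replicates 1, 2 or 3 or E18.5 bladder replicate 1 or E18.5 urethral replicates 1 or 3 (camera adjusted p = 0.0894 to 0.396), erythroid genes at E14.5 without E14.5 urethral replicate 1 (adjusted p = 0.0697), cartilage genes at E18.5 without E18.5 bladder replicate 1 or E18.5 urethral replicate 3 (adjusted p = 0.0622 to 0.0899) and adipocyte genes in bladder without E18.5 bladder replicate 2 (adjusted p = 0.0582).

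Haemoglobin genes took 0.1399 ± 0.0165% of counts in E14.5 bladder and 0.0929 ± 0.0216% in E14.5 urethral mesenchyme (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow), and 0.0694 ± 0.0159% and 0.07403 ± 0.00261% at E18.5 (exact permutation p = 1). As a check of the female label, the Y-linked list held 0 to 11 counts per library. Xist ranged from 258 to 1697 CPM. The highest was E14.5 urethral replicate 2, whose group had 309.9 and 484 CPM in the other libraries. Other noncoding RNAs, named after their values were seen, were also highest there within the group. In replicate 2, Malat1 had 485 CPM against 155 and 177 in replicates 1 and 3, Meg3 539.8 CPM against 135 and 107, Miat 117 CPM against 12.7 and 25.2 and Kcnq1ot1 43.02 CPM against 16.9 and 13.6. The cause was not tested. Without that library, 1937 genes were higher in E14.5 bladder and 2065 in E14.5 urethral mesenchyme.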
